A study of Mus musculus with 8 samples.

How the data were processed

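Total RNA of mouse EDL muscle was purified with a column kit for fibrous tissue and turned into biotinylated cRNA for Illumina arrays, per the labels' protocols. The samples fall into 4 Sod1 knockout and 4 wild-type arrays by their titles, all from mice aged 7 months. The values used are the authors' deposited log2 intensities. All 8 columns hold the same sorted values, with a median of 6.93, a lowest value of 3.21 and a highest of 14.19, so the deposited log2 values were quantile normalized across arrays. That the base of the logarithm is 2 was judged from this range. Background correction, the log transform and any probe filter before deposit are not given in the sources used here, and no further normalization was applied. Quantile normalization gives each array the same overall distribution, so a shift of all transcripts in a sample cannot be seen, and 121 tested probes with a mean above 13 lie near the ceiling, where differences are compressed. A table of values not brought to a common distribution was not used: its 8 columns carry names that match no sample's labels. The test had been planned on that table, and the plan named the normalized values as the substitute. Replicate numbers were checked for pairing and were not used as pairs.

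Of the 9232 probes, 8403 had 1 gene name in the platform annotation, 3 had several and 826 had none; 8399 of the named probes matched the mouse GRCm38.p6 gene table by Entrez number, and 0 symbols changed. They stand for 7053 genes. Probes above the array's median in at least 4 of the 8 arrays, whatever their group, were tested: 4698 probes, 4309 of them with a gene name, for 3823 genes. Of these genes 427 had several tested probes, and the probe of highest mean over all arrays stood for the gene. Other tested probes were compared only for genes named by the fixed rule below, not for genes chosen after their values were seen. Where a gene named by that rule had another tested probe, that probe differed in the same direction. This was not so for Srxn1 and Prdx2, which the fixed naming rule allowed but the shortened text left out. Srxn1 differed by -0.60 and its other probes by 0.01 and 0.22, and Prdx2 by 0.33 and its other probe by -0.02. Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit with a term for genotype, then eBayes without trend), two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all tested probes. Each difference is knockout minus wild type on the log2 scale, and SD is over the 4 arrays of a genotype.

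A set of 30 gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The 24 lists with at least 5 tested members were compared with all other genes by limma's camera with a preset correlation of 0.01, Benjamini-Hochberg adjusted over the 24. Camera compares a list with the other genes, whose median difference was -0.04, so its direction can differ from the sign of the list mean; this was so for antioxidant enzymes, NRF2 target genes, oxidative phosphorylation and the neighbours of Sod1. The same lists were tested with a correlation estimated from the data and with fry. A list's value in an array is the mean over members of the log2 intensity minus the wild-type mean, compared by an exact permutation test over the 70 arrangements of the labels.

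The naming rule placed Sod1 first, then up to 15 genes per direction among probes past the adjusted threshold with no overlap between genotypes. If under 5 probes passed in a direction, the 10 genes of smallest unadjusted p in it were named as not passing, which is what applied. Each list allowed up to 4 members of smallest p. After the results were seen, 4 were named for the lists that passed camera and 2 for the others, to keep the text short. Genes known only by a numbered or predicted name were counted and not named. Genes named outside this rule are said to have been chosen after their values were seen.

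The procedure was tested on simulated data for the comparison of knockout and wild type, 20 simulations of the 4698 tested probes with 200 changed. It recovered 63.5% of the probes changed 2-fold and 93.9% of those changed 4-fold, and 5.20% of its calls were false. The shifted list was found in 20 of 20 simulations among 24 lists, with 0.2 other lists called per simulation. The simulated noise was independent between probes. Members of the real lists were correlated, at an estimated 0.35 for denervation-responsive genes and 0.78 for proteasome subunits. The simulated rates of false calls therefore cannot be carried over to the real arrays. Nor can the recovered shares, which also depend on how many probes are changed, 200 here. The simulated list was shifted by more than the mean of any real tested list differed. Alternatives covered the filter, the moderation, array weights, a replicate block, a mean per gene, each array left out in turn and the tests of lists. Added after the data were seen were cyclic loess on top of the deposited values, leaving out both arrays of lowest estimated weight, the permutation test of list means, and marker lists without the filter. No coordinates are given, since no build is named for the array.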

Results

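The extensor digitorum longus (EDL), a fast-twitch muscle of the lower hind limb, was profiled on Illumina bead arrays in mice lacking Sod1, the copper-zinc superoxide dismutase that removes superoxide from the cytosol, and in wild-type mice. The series asks how skeletal muscle transcription responds to lasting oxidative stress. There were 4 arrays per genotype and 8 in all, from muscle of mice aged 7 months. The level of Sod1 was not analysed here, so the genotype labels were not checked against the targeted gene. The values covered 9232 probes, of which 8403 carried 1 gene name. The labels do not state that the samples of a genotype came from separate animals, so p-values measure the spread between these samples. The number of arrays limits the precision: the median standard error of a difference between genotypes was 0.21 on the log2 scale. Array profiles correlated across the tested probes, which are not independent replicates, at Pearson r from 0.911 to 0.969 within the knockout, from 0.906 to 0.968 within the wild type and from 0.863 to 0.97 between genotypes.

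The probe of Myl12a, a regulatory light chain of non-muscle myosin, showed the smallest p of all probes. Its log2 intensity was 9.74 ± 0.46 (SD, n = 4) in the knockout and 7.87 ± 0.37 in the wild type, a 3.65-fold difference. Rpl3, a protein of the large ribosomal subunit, stood at 11.73 ± 0.24 against 10.41 ± 0.34, a 2.50-fold difference. Fez1, Scd1 and Lgmn were each more than 1 log2 unit above the wild type: Fez1, an adaptor in axonal transport, by 1.14, Scd1, a fatty acid desaturase, by 1.02, and Lgmn, a lysosomal protease, by 1.22. Sbk1, a protein kinase, differed by 1.01 and Dtna, the alpha-dystrobrevin of the dystrophin complex, by 0.91. Mapt, the microtubule protein tau, differed by 0.89, Pfn1, an actin-binding profilin, by 0.80 and Dhrs4, a carbonyl reductase, by 0.61. Second probes of Mapt, Fez1 and Dtna differed in the same direction, by 0.61, 1.28 and 1.29.

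Among the genes with the smallest p on the lower side, Sctr, the secretin receptor, had a log2 intensity of 7.78 ± 0.42 (SD, n = 4) in the knockout and 8.76 ± 0.20 in the wild type. Arfgap1, which acts on the Golgi GTPase Arf1, differed by -0.91 and Ccng2, an unconventional cyclin, by -0.83. Myl10, a myosin light chain, differed by -0.83. Kat8, a histone acetyltransferase, and Eed, a subunit of the Polycomb complex PRC2, differed by -0.67 and -0.63. Gtdc1 differed by -0.66, Adcy4, an adenylate cyclase, by -0.65, Ppp1r35 by -0.64 and Rab33b, a Golgi Rab protein, by -0.63. In each of the 20 genes named so far, all 4 knockout values lay on the same side of all 4 wild-type values.

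None of these genes passed the test over all probes. With limma and Benjamini-Hochberg adjustment, 0 of 4698 tested probes had an adjusted p under 0.05, and the smallest adjusted p was 0.219, for Myl12a. At an unadjusted p under 0.05 there were 439 probes, 223 higher and 216 lower in the knockout, where 234.9 are expected by chance. The genotypes did not overlap at 216 probes, or 4.60% of those tested, where chance gives 2.86%. Both expected values are averages without a spread. Of the 35 splits of the 8 arrays into 4 and 4, run after the results were seen, 6 gave at least 439 probes. At least 216 probes without overlap came from 9 of the 35, the real split included in each count. Neither count therefore sets the genotypes apart from other groupings. The splits that matched the 439 probes were not all unrelated to genotype. Those with knockout replicates 1, 3 and 4 beside wild-type replicate 2, 3 or 4 gave 584, 616 and 508 probes. Splits with 2 knockout arrays on each side matched it as well, with 655 and 465. The count of 0 depended on the arrays: without knockout replicate 2 it was 36, with 33 probes higher and 3 lower, Myl12a, Rpl3, Fez1, Lgmn, Dtna, Pfn1 and Sctr among them, and with array weights estimated from the data it was 4.

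**Figure D1:**
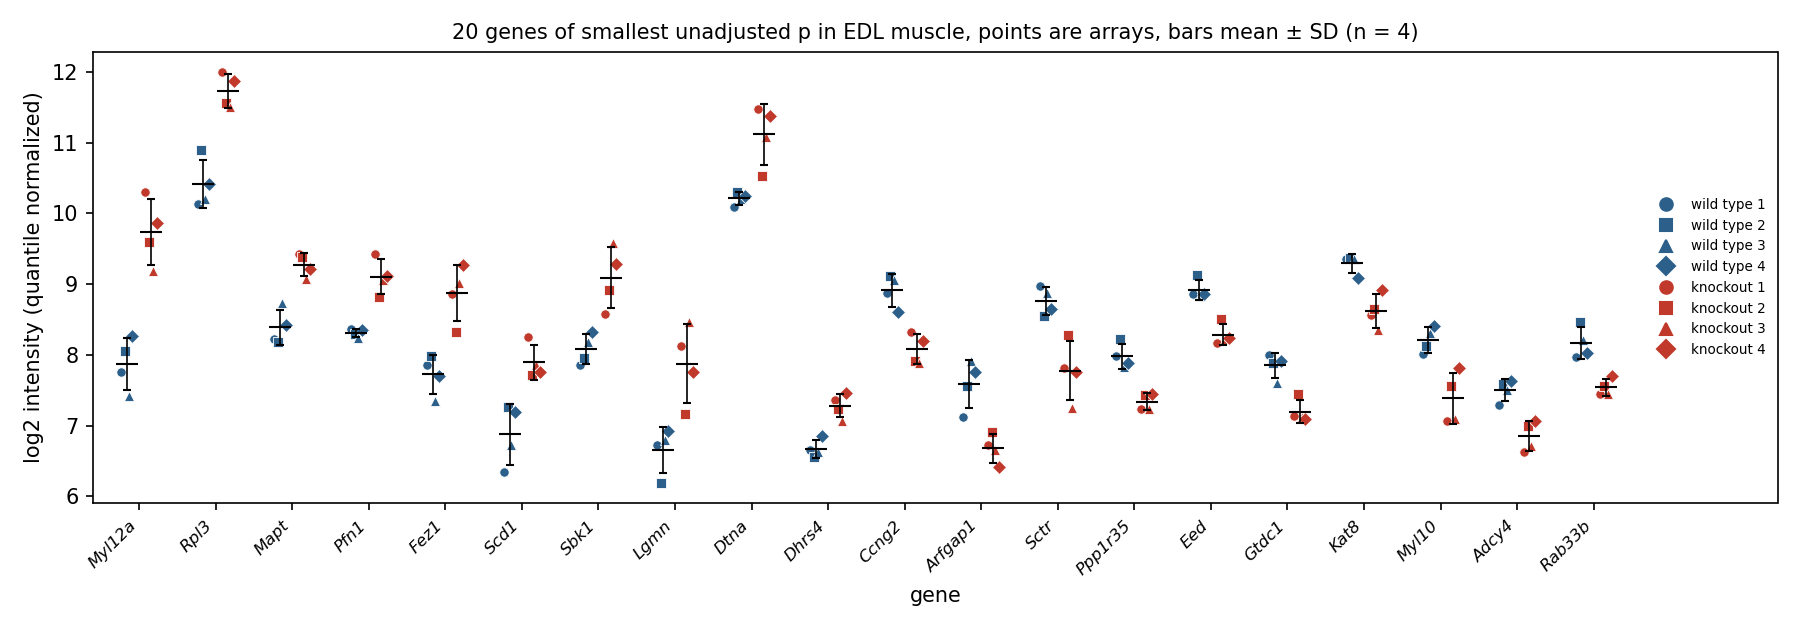
Log2 intensity (y axis) of the 20 genes of smallest unadjusted p, 10 in each direction (x axis), in 4 wild-type (blue) and 4 knockout (red) arrays; points are arrays, and bars are the mean ± SD. Myl12a stands at 9.74 in the knockout against 7.87 in the wild type, and no gene passed the adjusted threshold.

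Denervation-responsive genes rose relative to other genes by camera with its preset correlation (adjusted p 0.0137). That call was lost with an estimated correlation (adjusted p 0.729). With the preset correlation, 34 of the 35 splits of the 8 arrays into 4 and 4 gave at least 2 lists, the real split included. A camera call, here or for the lists below, therefore does not by itself set the genotypes apart. Tests of a change in the list itself, which do not compare it with other genes, gave an adjusted p of 0.668 with fry and an exact permutation p of 0.0571 for the list mean (two-sided). Of 9 tested members, 8 had a higher mean in the knockout, and the list mean differed by 0.92 log2 units (knockout SD 0.74, wild-type SD 0.38, n = 4). Ankrd1, a stress-responsive ankyrin repeat protein, stood at 11.54 ± 1.01 against 8.56 ± 1.60. Chrna1 and Chrnb1, subunits of the muscle acetylcholine receptor, stood at 11.21 ± 1.5 against 9.36 ± 0.09 and at 9.07 ± 0.66 against 8.14 ± 0.20, and a second probe of Chrna1 differed by 2.09. Hdac4, a histone deacetylase that acts downstream of nerve activity, stood at 9.57 ± 1.06 against 8.73 ± 1.01. No member passed over all probes, and Ankrd1, Chrnb1 and Chrna1, 3 members, passed when adjusted over the list alone; without knockout replicate 2, Chrna1 (adjusted p 0.000749) and Chrnb1 (0.0284) passed over all probes. In knockout replicate 2 the list mean was -0.06, inside the wild-type range, and its members were mixed. Chrna1 was 12.25, 11.62 and 11.98 in replicates 1, 3 and 4, and 8.98 in replicate 2, below the wild-type values of 9.24 to 9.43, whereas Ankrd1 was 12.21 in replicate 2, the highest of all arrays, and Rapsn, which was chosen after its values were seen, was 9.05, also the highest. For Rapsn the other knockouts, at 8.23 to 8.70, lay inside the wild-type range of 7.60 to 8.96. The camera call was lost without knockout replicate 1, with a shift of 0.68 and an adjusted p of 0.0679, and without wild-type replicate 2, with a shift of 0.88 and an adjusted p of 0.0621; the adjusted p over all alternatives ran from 3.17e-05 to 0.729.

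**Figure D2:**
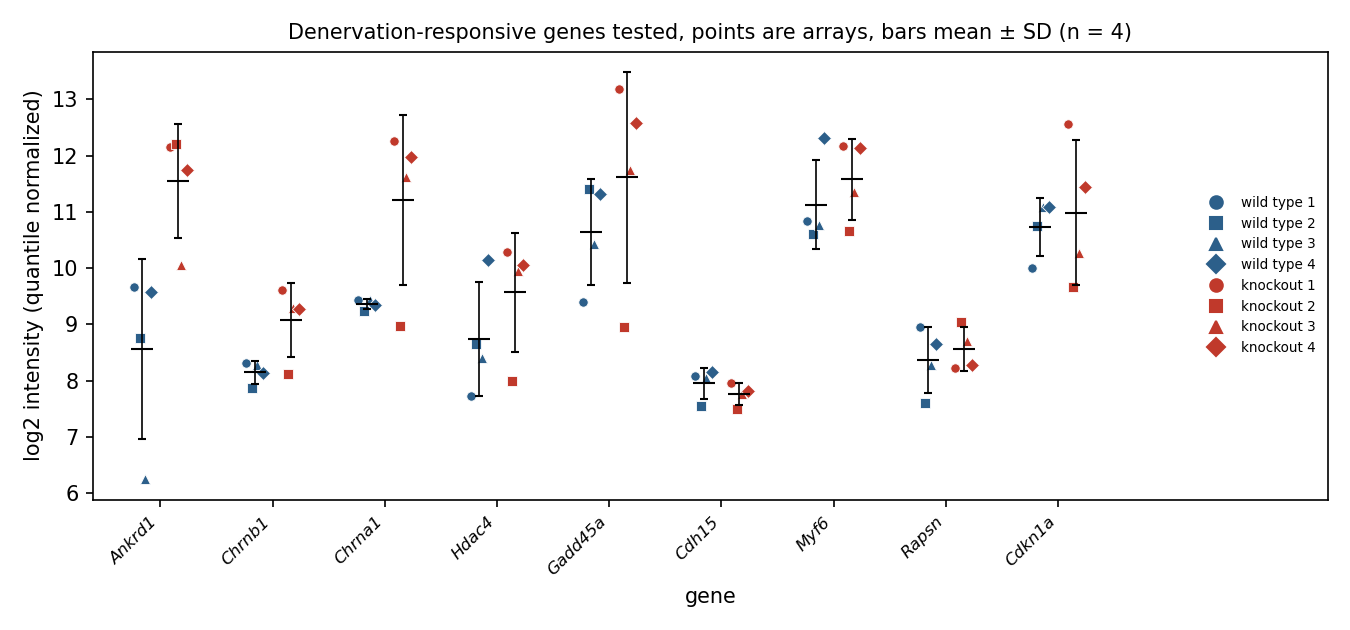
Log2 intensity (y axis) of the 9 tested denervation-responsive genes (x axis) in 4 wild-type (blue) and 4 knockout (red) arrays; points are arrays, and bars are the mean ± SD. Knockout replicate 2, the red square, stands at 8.98 for Chrna1, where the other knockout arrays lie between 11.62 and 12.25.

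Slow fibre genes, those typical of oxidative type I fibres, rose relative to other genes by camera with its preset correlation (adjusted p 0.0296). That call was lost with an estimated correlation (adjusted p 0.729). The tests of a change in the list itself gave an adjusted p of 0.668 with fry and an exact permutation p of 0.143 for the list mean (two-sided). Of 11 tested members 9 were higher in the knockout, with a list mean difference of 0.31 (knockout SD 0.39, wild-type SD 0.07, n = 4). The members of smallest p were Atp2a2, the slow sarcoplasmic calcium pump, with a difference of 1.09, Csrp3, a Z-disc LIM protein, with 1.47, Fhl1, another LIM protein, with 0.49, and Lmcd1 with 1.09. Contractile members, chosen after their values were seen, moved less: Tnnt1 differed by 0.25, Tnnc1 by 0.06 and Myl2 by -0.15. Below the filter, Myh7 differed by 0.77 and Tnni1 by 0.86. The list call was not read as a change of fibre type. Myl3, a slow myosin light chain chosen after its values were seen, was 5.46, 5.92 and 6.30 in knockout replicates 1, 3 and 4 and 9.11 in replicate 2, with wild-type values from 7.50 to 8.24; it did not pass, but did so as lower without knockout replicate 2 (-1.97, adjusted p 0.0146 over all probes). The number of members past the threshold was 0 over all probes and 0 when adjusted over the list alone. The list mean was highest in knockout replicate 2, at 0.77 above the wild-type mean, and the call was lost without it, with a shift of 0.16, as it was without knockout replicate 1 (0.30) and without wild-type replicate 2 (0.32), and without both replicates numbered 2 (0.17, adjusted p 0.243); the adjusted p over all alternatives ran from 0.000274 to 0.729. Fast fibre genes, the main set of this muscle, had 13 of 17 members higher, a difference of 0.16 and a camera adjusted p of 0.0614. They passed without knockout replicate 4 (adjusted p 0.0333), wild-type replicate 1 (0.0368) or wild-type replicate 3 (0.0188), and with the stricter filter (0.0456). Their mean was lowest in wild-type replicate 2, at -0.26, and the difference shrinks without that array. Many fast fibre members lay near the ceiling of the values, where differences are compressed. Tnnc2 stood at 13.97 in the knockout against 13.78 in the wild type and Pvalb at 14.01 against 13.95, both chosen after their values were seen. Myl1, a fast myosin light chain, differed by 0.41 and Pdlim3 by 0.53, and neither passed.

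Immature and regenerating fibre genes had 7 of 9 members higher in the knockout and a list mean difference of 0.34, with a camera adjusted p of 0.166. Without knockout replicate 2 the difference was 0.56 and the list passed (adjusted p 0.0208), as it did without both replicates numbered 2 (0.64, adjusted p 0.00672) and without the filter (0.60, adjusted p 0.0481). Myl4, the embryonic and atrial myosin light chain, stood at 10.56 ± 0.57 (SD, n = 4) against 9.49 ± 0.30 and was the 1 member that passed when adjusted over the list alone, with 0 over all probes; without knockout replicate 2 it passed over all probes (adjusted p 0.0284). Igf2, a growth factor of developing muscle, stood at 9.88 ± 0.78 against 8.96 ± 0.46. Of the satellite cell markers 3 were tested, too few for camera, and their mean differed by -0.04; Cdh15 differed by -0.19 and Des by 0.13. Myokine and growth control genes differed by 0.22 (6 of 10 higher, camera adjusted p 0.198), with Il15, a cytokine made by muscle, at 7.55 ± 0.74 against 6.72 ± 0.27 and no member past the threshold. The list mean was highest in knockout replicate 3, at 0.56, and lowest in wild-type replicate 2, at -0.435. Without either array the difference shrinks.

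Genes of the antioxidant defence did not move together. Among 19 antioxidant enzymes, 9 were higher and 10 lower, with a mean difference of -0.02 and a camera adjusted p of 0.712. Gsr, glutathione reductase, stood at 7.75 ± 0.54 (SD, n = 4) against 8.63 ± 0.36, and Gpx1, the main cytosolic glutathione peroxidase, at 11.23 ± 0.29 against 10.71 ± 0.23; neither passed. NRF2 target genes, which respond to electrophiles and oxidants, differed by -0.06 (6 of 15 higher, camera adjusted p 0.75), with Gsta4, a glutathione transferase, at 0.96 and Aox1 at 0.57. Metallothionein and metal handling genes differed by 0.07 (6 of 10 higher, camera adjusted p 0.598), with the iron exporter Slc40a1 at -0.58 and the zinc importer Slc39a1 at 0.29. The p53 target genes differed by 0.26 (5 of 7 higher, camera adjusted p 0.198), with Ccng1 at 0.43 and Ei24 at 0.32. Their mean was 0.98, -0.485, 0.004 and 0.56 in knockout replicates 1 to 4, so the difference shrinks without replicate 1 and grows without replicate 2. The p53 list passed without the filter (0.30, adjusted p 0.0481). The sign of the mean turned for antioxidant enzymes without wild-type replicate 4 (0.0109), for NRF2 target genes without knockout replicate 3 (0.024) or wild-type replicate 2 (0.0080), and for metal handling without knockout replicate 4 (-0.0034) or wild-type replicate 1 (-0.0205). In these 4 lists 0 members passed over all probes and 0 when adjusted over the list alone.

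Energy metabolism lists differed from the wild type by at most 0.13 in their means. Oxidative phosphorylation, with 52 members tested and 22 higher, differed by -0.01 (camera adjusted p 0.75); the complex I subunits Ndufa8 and Ndufb3 differed by 0.33 and 0.29. Glycolysis and glycogen genes differed by 0.04 (14 of 22 higher, camera adjusted p 0.24), with Ldhb, the heart-type lactate dehydrogenase, at 0.43 and Hk2, a hexokinase, at 0.38; without wild-type replicate 3 the difference was 0.14 and the list passed (adjusted p 0.0463). Fatty acid uptake and oxidation genes differed by -0.09 (8 of 25 higher, camera adjusted p 0.914), with Mlycd, malonyl-CoA decarboxylase, at -0.53 and the transporter Slc27a1 at -0.41. Citric acid cycle and mitochondrial biogenesis genes differed by 0.13 (14 of 21 higher, camera adjusted p 0.114), with Mdh1 at 0.66 and Sucla2 at 0.74. The list passed without knockout replicate 4 (adjusted p 0.0333), wild-type replicate 1 (0.0368) or wild-type replicate 3 (0.0296). Its mean was lowest in wild-type replicate 2, at -0.23, and the difference shrinks without that array. The sign turned for glycolysis without wild-type replicate 2 (-0.035), for fatty acid oxidation without knockout replicate 3 (0.054), and for oxidative phosphorylation without knockout replicate 2 (0.035) or 4 (0.013) or wild-type replicate 1 (0.015) or 4 (0.015). No member of these lists passed, over all probes or adjusted over the list alone. Many oxidative phosphorylation and glycolysis members lay near the ceiling of the values, where differences are compressed. Cox8b stood at 13.98 in the knockout against 14.02 in the wild type and Gapdh at 14.1 against 14.06, both chosen after their values were seen.

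Muscle atrophy, ubiquitin and autophagy genes had 17 of 21 members lower in the knockout, with a mean difference of -0.30 and a camera adjusted p of 0.166. The difference rested on knockout replicates 2 and 3, at -0.53 and -0.80. Replicates 1 and 4 stood at 0.14 and -0.01, with wild-type values from -0.30 to 0.36. Bnip3l, a mitophagy receptor, differed by -0.68 and Map1lc3b, an autophagosome protein, by -0.64. Proteasome subunits had 22 of 26 lower, a difference of -0.15 and a camera adjusted p of 0.198, with Psmd12 at -0.42 and Psmd7 at -0.26. The list passed as lower without knockout replicate 2 (-0.27, adjusted p 0.022), wild-type replicate 3 (-0.24, adjusted p 0.0187) or wild-type replicate 4 (-0.25, adjusted p 0.0254). Its mean was highest in wild-type replicate 2, at 0.40, and lowest in knockout replicate 3, at -0.45. The difference shrinks when either of these arrays is left out. Heat shock proteins and chaperones differed by 0.10 (14 of 21 higher, camera adjusted p 0.22), with Hspb8, a small heat shock protein, at 0.38 and Dnaja4 at 0.80; knockout replicate 2 stood at 0.48, the other knockouts at -0.07 to 0.06, and without replicate 2 the list differed by -0.023. ER stress and ATF4 targets differed by -0.30 (7 of 10 lower, camera adjusted p 0.279), with Eif4ebp1, a repressor of translation, at -0.86 and the chaperone Hsp90b1 at -0.31. Their mean was -0.44 and -0.755 in knockout replicates 2 and 3, and 0.01 and -0.01 in replicates 1 and 4. Ribosomal proteins differed by -0.01 (11 of 30 higher, camera adjusted p 0.887), and by 0.046 without wild-type replicate 4. Rpl3, which passed when adjusted over that list alone, was the 1 member of these 5 lists to pass in either way, and passed over all probes without knockout replicate 2 (adjusted p 0.0380); Rps6 differed by -0.25.

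Markers of other cells and tissues were set beside these lists. Adipocyte markers differed by 0.54 (3 of 7 higher, camera adjusted p 0.151), while the median member differed by -0.01; the list passed without knockout replicate 3 (0.66, adjusted p 0.0202), with array weights (0.74, adjusted p 0.0388) and without both replicates numbered 2 (0.84, adjusted p 0.033). Scd1 and Car3, 2 members, passed when adjusted over the list alone and 0 over all probes; Car3, a carbonic anhydrase also abundant in muscle, stood at 13 ± 1.05 (SD, n = 4) against 11.18 ± 0.54, near the ceiling of the values (14.19, the highest in any array), and its second probe differed by 3.17 (limma unadjusted p 0.000146), without passing over all probes. Without knockout replicate 2 both probes of Car3 passed (adjusted p 0.0146 and 0.00280). Macrophage and leukocyte markers numbered 4, too few for camera, all higher, with a mean difference of 0.78 and an exact permutation p of 0.0571 (two-sided; the smallest that 4 against 4 allow is 0.0286). Cd74, the invariant chain of MHC class II, stood at 7.90 ± 0.84 against 6.76 ± 0.40, and Lgals3, a macrophage galectin, at 9.68 ± 1.10 against 8.55 ± 0.49, past the threshold over all probes without knockout replicate 2 (adjusted p 0.0471). Endothelial and pericyte markers had 10 of 11 lower, a difference of -0.22 and a camera adjusted p of 0.198, with Vwf at -0.49 and Cdh5 at -0.25; the list passed as lower without knockout replicate 4 (-0.37, adjusted p 0.03), without wild-type replicate 1 (-0.32, adjusted p 0.0457) and without the filter (-0.30, adjusted p 0.0109). Extracellular matrix and fibrosis genes differed by 0.04 (7 of 12 higher, camera adjusted p 0.712), with Col4a2 at 0.40 and Dcn at -0.24, and by -0.040 without knockout replicate 2 and -0.13 without wild-type replicate 1. The nerve and Schwann cell markers Pmp22 and Art3 differed by -0.86 and -0.31, and the 4 interferon response genes by 0.07 on average, with Irgm1 at 0.34 and Ifi27 at 0.21.

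In the lists kept as checks on the samples no member passed. Erythrocyte markers, 4 tested, differed by -0.30, with Alas2 at -0.38 and Hba-a1 at -0.32. The Y-linked gene Eif2s3y lay between 8.63 and 9.05 in all 8 arrays. Clock genes differed by -0.08 (6 of 13 higher, camera adjusted p 0.951), with Nfil3 at -0.79 and Nr1d1 at 0.72, and by 0.056 without knockout replicate 3 and 0.00099 without wild-type replicate 3. Immediate early genes had 8 of 9 lower, a difference of -0.32 and a camera adjusted p of 0.166, with Ier3 at -0.90 and Jun at -0.25; the list passed as lower without wild-type replicate 1 (-0.47, adjusted p 0.0368). The neighbours of Sod1 on its chromosome differed by -0.0016 on average (4 of 9 higher, camera adjusted p 0.887), with Bach1 at -0.40 and Cct8 at 0.21, and turned to between 0.0077 and 0.043 without knockout replicate 1, 3 or 4 or wild-type replicate 1 or 4.

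**Figure D3:**
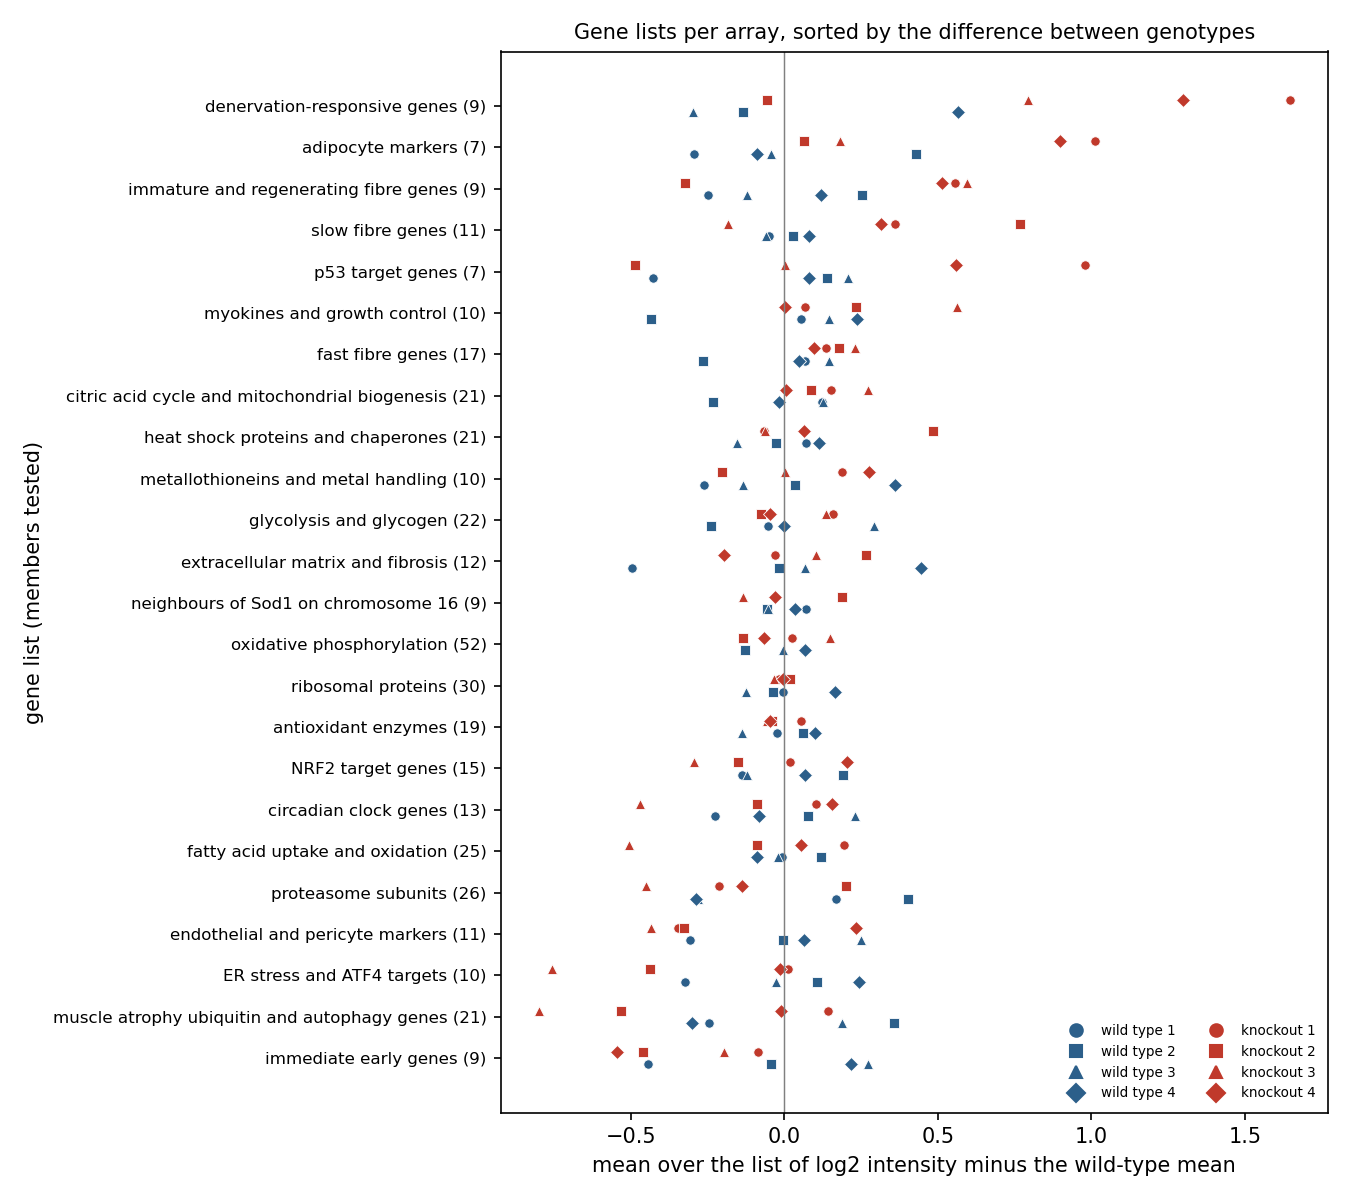
Mean log2 intensity of each tested list minus its wild-type mean (x axis) for the 24 lists with at least 5 tested members (y axis, number tested in parentheses), in 4 wild-type (blue) and 4 knockout (red) arrays; points are arrays. For denervation-responsive genes 3 knockout arrays lie between 0.79 and 1.65, and knockout replicate 2 lies at -0.06.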

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

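In 17 of the 218 groups of 4 arrays checked, for the named genes and the list means, the highest or lowest array stood far from the other 3; chance does so in about 1 in 20 groups, or 10.9 here. Knockout replicate 2 was that array in 6 of the 17 and wild-type replicate 2 in 3. No explanation is weighed for single genes.

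Knockout replicate 2 was apart from the other knockout arrays for Gtdc1 (7.44, others 7.09 to 7.13), Hdac4 (8, others 9.95 to 10.29), Igf2 (8.72, others 10.12 to 10.37), Car3 (11.44, others 13.30 to 13.68) and Jun (7.41, others 8.01 to 8.11). Its mean of immature and regenerating fibre genes was -0.32, with the others at 0.51 to 0.60. Knockout replicate 3 was apart for Fhl1 at 13.12, Mlycd at 10.69, Irgm1 at 7.80 and Il15 at 8.65. The mean of antioxidant enzymes was 0.05 in knockout replicate 1, with the others at -0.06 to -0.04, and that of endothelial and pericyte markers was 0.23 in knockout replicate 4, with the others at -0.43 to -0.32.

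Among wild-type arrays, replicate 2 was apart for Eed at 9.13, for Gsta4 at 7.59 and for the mean of the nerve and Schwann cell markers at -0.76, with the others at 0.21 to 0.28. Kat8 was 9.09 in wild-type replicate 4, and Cdh5 was 6.89 in wild-type replicate 1.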

How the results depend on the processing

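Cyclic loess, leaving out 2 arrays together and the permutation test of list means were chosen after the data were seen. With limma, 0 probes passed in every alternative except array weights (4), without knockout replicate 2 (36) and without both arrays of lowest weight, knockout replicate 2 and wild-type replicate 2 (59); leaving out each array gave 0 to 36. The count at unadjusted p under 0.05 was 961 without a filter, where 9232 probes were tested, 693 without both arrays, and 255 (without knockout replicate 3) to 674 (without knockout replicate 2) when each array was left out. Camera called 6 lists without a filter (p53 targets, denervation-responsive, immature fibre, slow fibre, leukocyte, and endothelial genes, the last lower), 3 without both arrays (denervation-responsive, immature fibre and adipocyte genes), and 0 with an estimated correlation. Fry, which tests a list against no change and not against other genes, called 0. The exact permutation of list means asks the same of each list; its p cannot fall below 0.0286, so its count over 24 lists is not read. Leaving out each array gave 0 to 6: 0 without knockout replicate 1 or wild-type replicate 2, 5 without knockout replicate 4, and 6 without wild-type replicate 1 or 3. The cause was not tested, except that leaving out arrays or the filter changes the arrays or probes tested.

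Of the genes named by the rule, as shortened after the results were seen, none changed sign in any alternative. They were picked for small p in these same arrays, so their stable signs are no independent support. The named genes past the threshold numbered 12 without knockout replicate 2, 14 without both arrays (Igf2, Atp2a2 and Pmp22 entered, Pfn1 did not pass) and 2 with array weights. List means near 0 changed sign. With array weights these were antioxidant enzymes 0.0062, NRF2 targets 0.037, glycolysis -0.030 and extracellular matrix -0.059. With the mean per gene they were antioxidant enzymes 0.0012 and NRF2 targets 0.0101. Without both arrays they were antioxidant enzymes 0.0028, NRF2 targets 0.0398, heat shock proteins -0.032 and extracellular matrix -0.046. Metal handling was -0.023 with the stricter filter. With cyclic loess oxidative phosphorylation was 0.0041, neighbours of Sod1 0.019 and ribosomal proteins 0.0041.

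Over the fits that leave out an array, antioxidant enzymes ranged from -0.069 to 0.0109, NRF2 targets from -0.14 to 0.024, metal handling from -0.0205 to 0.19, glycolysis from -0.035 to 0.14, oxidative phosphorylation from -0.058 to 0.035, and fatty acid oxidation from -0.18 to 0.054. Heat shock proteins ranged from -0.023 to 0.16, extracellular matrix from -0.13 to 0.18, clock genes from -0.15 to 0.056, neighbours of Sod1 from -0.065 to 0.043 and ribosomal proteins from -0.0506 to 0.046.

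Same-numbered arrays did not deviate together (correlations across probes -0.28, -0.15, 0.24 and -0.34), so the numbers are not read as pairs; with the replicate block 0 probes passed and camera called 1 list (denervation-responsive genes; slow fibre genes had an adjusted p of 0.0843). Not run were the other background corrections, median scaling and no normalization, which need the unused table, and a chip block, since no chip is named. Dim probes limit what can be read: 4534 fell below the filter.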

Other observations

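The genes named in this part, the splits, the positions, the marker comparisons without the filter and the permutation tests were chosen after the results were seen; leaving out an array in limma and running camera without the filter were fixed before. Several genes, picked because they resembled Chrna1 and so no evidence for a theme, parted knockout replicate 2 from the other knockouts. Ncam1, a cell adhesion molecule, was 9.32, 8.71 and 9.03 in knockout replicates 1, 3 and 4 and 5.95 in replicate 2, with wild-type values from 5.35 to 6.65. Myh3, the embryonic myosin heavy chain, was 9.55, 8.84 and 8.79 against 5.65 in replicate 2; both lay below the filter. Aif1l (11.12, 10.16 and 10.48 against 5.56), Igfn1 (10.21, 9.52 and 10.32 against 6.41), Fggy (9.62, 9.26 and 9.30 against 6.93) and Hes6, a repressor in the Notch pathway (9.73, 9.93 and 9.74 against 7.40), were arranged likewise. Of the denervation-responsive genes below the filter, Chrne was arranged likewise but by a narrow margin (7.05, 6.63 and 6.46 against 5.05, with wild-type values from 5.16 to 6.43). Lrp4 and Agrn were not arranged so. Lrp4, a receptor at the neuromuscular junction, was 6.82 in knockout replicate 2, the highest of all arrays, with wild-type values from 4.79 to 5.70. Agrn was 6.43 in that array, with wild-type values from 6.04 to 6.99. Of the 36 probes that passed without knockout replicate 2, that array lay within or beyond the wild-type range on the wild-type side at 23.

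Other genes parted the arrays across genotype, in different ways. Dkk3 set wild-type replicate 2 with knockout replicates 1, 3 and 4. Sesn1 and Trim63 set wild-type replicates 2 and 3 with knockout replicates 1 and 4. Dkk3, a secreted Wnt modulator, was 5.84, 11.07, 6.16 and 5.92 in knockout replicates 1 to 4 and 11.58, 5.96, 11.84 and 11.89 in the wild type. Sesn1, a stress-induced gene, was 11.73, 9, 8.32 and 11.35 in the knockout and 9.18, 11.77, 11.43 and 8.88 in the wild type. Trim63, a ubiquitin ligase of atrophy, was 11.65, 8.52, 8.60 and 10.78 and then 9.42, 11.28, 11.41 and 9.85.

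Chance could not be excluded for 3 of the counts by genotype. The 439 probes at unadjusted p under 0.05 were matched by 6 of the 35 splits of the 8 arrays into 4 and 4 (the real one included), with a highest other of 655, the 2 camera lists by 34 of 35, with a highest other of 8, and the 216 probes without overlap by 9 of 35, with a highest other of 399. For the 0 probes past the adjusted threshold the splits decide nothing, since all 35 must give at least 0; the highest other gave 31. That split is the genotype split with knockout replicate 2 and wild-type replicate 2 exchanged. At unadjusted p under 0.05 it gave 584 probes. Splits with knockout replicates 1, 3 and 4 beside wild-type replicate 3 or 4 gave 616 and 508. Not every matching split was thus unrelated to genotype. The 655 and 399 came from a different split, which set knockout replicates 1 and 4 with wild-type replicates 2 and 3. It gave 16 probes past the adjusted threshold. The arrays thus vary in more ways than the genotype labels follow. The cause was not tested, beyond the placing of knockout replicate 2 and wild-type replicate 2 below.

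The mean of the denervation-responsive genes stood at the wild-type level in knockout replicate 2. In that array 3 of the 9 members, Ankrd1, Cdh15 and Rapsn, lay beyond every wild-type array on the side of the mean of the other knockouts. For Cdh15 and Rapsn that side means little, since the other knockouts lay inside the wild-type range. Cdh15 was also lower, against the direction of the list, so only Ankrd1 was placed with the knockouts. To place each array, the 100 probes of smallest p were chosen without it and without knockout replicate 2, with 0 at the wild-type mean and 1 at the knockout mean; an earlier version, which left out only the placed array, gave 0.113 for knockout replicate 2 and 0.225 to 0.669 for the wild-type arrays, and the axis was revised after that was seen. The median position of knockout replicate 2 was 0.113, against 0.0984 to 0.466 for the wild-type arrays and 0.747 to 0.914 for the other knockouts held out in the same way. A wild-type sample carrying a knockout label is a candidate explanation, and a knockout muscle without most of the change, which no group tests, could give the same position. Single probes were mixed. Of the 33 probes that passed as higher without knockout replicate 2, that array lay above every wild type at 12. Of the 3 lower ones it lay below every wild type at 1. At the other 23 it lay within or beyond the wild-type range on the wild-type side. Its label was not settled. An exchange with wild-type replicate 2, at 0.466 with quartiles of 0.0883 and 0.714, cannot be told apart from no exchange, because its quartiles lie on each side of the midpoint.

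Leukocyte markers, with dim probes kept, were higher in the knockout by 0.61 (SE 0.26), with 18 of 19 genes higher and an exact permutation p of 0.0857 (two-sided, n = 4); against other genes, camera gave an adjusted p of 0.000174. Endothelial and pericyte markers differed in the other direction in the same arrays, with 19 of 21 lower and a mean difference of -0.30, the same exact permutation p of 0.0857 and a camera adjusted p of 0.0109. Both camera values rest on the preset correlation of 0.01. An estimated correlation, with which no list passed when the filter was applied, was not tried without the filter. Of the 19 leukocyte markers, 4 had passed the filter. The MHC class II genes H2-Eb1, H2-Ab1, H2-Aa and Cd74 averaged 1.24, and stood highest in knockout replicate 3, at 2.61. The other 15 markers differed by 0.44 (SE 0.25, exact permutation p 0.114), and knockout replicate 1, at 0.04 over all 19, lay inside the wild-type range of -0.39 to 0.35. Blood left in the tissue would bring erythrocyte transcripts with it, but their markers differed by -0.0908 (SE 0.20). That argues against blood as the source of the difference over all 19 markers. For the other 15 markers alone, the SEs of 0.25 and 0.20 are too wide to decide.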
